A study of Cicer arietinum with 12 samples.

How the data were processed

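Leaf DNA of chickpea (Cicer arietinum) was cut with MspI, which cuts CCGG also where the inner cytosine is methylated, treated with bisulphite and sequenced as reduced representation libraries (RRBS) in paired-end mode, per the labels' protocols. The 12 libraries came from 2 genotypes, the drought-sensitive ICC283 and the drought-tolerant ICC8261. Each genotype was grown well-watered at 80% of the soil's field capacity (WW) or drought-stressed at 20% (DS), with 3 libraries in each of the 4 groups. Pots were assigned to treatments at random, per the labels' protocols, and the labels do not say which pot a library came from. P-values therefore measure the spread between libraries.

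Trim Galore is the only tool named in the submitters' processing notes, with no version. The aligner, methylation caller, removal of duplicates and genome build are not given in the sources used here. Each deposited file listed methylated CpG calls of 1 library, with a fragment name, sequence name and position per call; every line carried the mark of a methylated CpG. Unmethylated calls were not analysed here. The files therefore gave counts of methylated calls, and neither the coverage of a site nor its methylation level could be computed. A count of methylated calls moves with methylation and with how often a fragment was sequenced, and a sequence difference at an MspI site or at a CpG moves it too. So does methylation of the outer cytosine of CCGG, which blocks MspI and was not measured in these files. The sequences were named Ca1 to Ca8 and a plastid sequence, and calls on Ca6 reached position 59463728. The reference table in hand belongs to the assembly Cicar.CDCFrontier_v2.0, which has genes beyond that position on Ca6. Positions are therefore given as in the deposited files, no gene was assigned to a region, and the planned tests of gene bodies, promoters and gene lists were not run.

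Calls on the 8 nuclear sequences were counted in windows of 200 bp, both strands together. Of 511306 windows with a call, 110038 had a mean of at least 10 calls over the 12 libraries and were tested. They held 73.5% to 78.1% of the nuclear calls of a library. The plan for files with methylated calls only was a packaged quasi-likelihood count test with at least 10 calls in each of the 12 libraries. Because the calls were counted here from lists, a quasi-Poisson log-linear model was written in R 4.3.3, with trimmed-mean scaling (30% of ratios and 5% of levels trimmed), variances moderated by limma 3.58.1 along the mean, and an F test. All 4 groups entered 1 fit, with the same residual degrees of freedom for every window. A group without calls adds nothing to the residual spread, so p-values of windows without calls in a group may be too small. The simulated changes below, 2-fold and 4-fold, did not cover such windows. Window levels are given as CPM, the calls in a window divided by the scaled library size and multiplied by 1000000. The minimum in each library was replaced by one on the mean, since it removes windows that lost their calls in a group. A window passed at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. The rule for named windows was the 5 largest folds each way past the threshold. A group without calls was given a floor of 3 calls over its libraries, so that folds against it are lower bounds; floors and intervals cover counting error only, and reads carried no molecular identifiers.

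A second measure was added after the data had been examined. Where 2 methylated calls of 1 fragment lay at most 50 bp apart on 1 strand, the CpG positions between them were taken as read. A position without a call there counted as missing. Which read of a pair held a call was not used, so part of these positions may not have been sequenced. The share of calls among those spanned positions, the spanned methylated share, is a percent computed here from the deposited calls and needs no coverage. It describes only fragments that carry methylation. Strand was assigned to 71.5% of 2062831 CpG positions, from the 1 bp step between the 2 cytosines of a CpG. Shares at 35795 positions with a mean of at least 5 spanning fragments were tested with limma on log2((calls + 1)/(missing + 1)), with a difference of at least 10 percentage points. This ratio rises with depth where no call is missing: of 7592 such positions, 820 had an unadjusted p under 0.05 in the ICC8261 drought comparison. An arcsine scale without that defect was therefore tried as the main scale, and was set aside because it did worse on simulated data.

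Values per library were compared by exact two-sided permutation tests, within strata where 2 pairs of groups were combined, with Benjamini-Hochberg adjustment over all 16 such tests. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Distinct positions were counted after thinning each library to 1770000 nuclear calls. The tests of windows and of positions were checked on simulated data for the ICC283 drought comparison. Simulated windows were counted at an adjusted p under 0.05 alone, without the 2-fold minimum. Over 110038 windows, the quasi-likelihood test recovered 69.0% of 200 windows changed 4-fold, with 24 false calls among 162, so that more than the nominal share was false, and 3.0% of 200 changed 2-fold. The genotype comparisons were simulated in the same way. Over 35795 positions, the log2 ratio recovered 191 of 200 positions whose share was set to 20%, with 12 false calls, and the arcsine scale 164 with 38 false calls. With independent positions at 90.0% the spanned share came to 90.0%, and it stayed at 90.0% when 20.0% of fragments carried no methylation, so that such fragments are not seen by this measure.

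Alternatives covered the minimum of calls, window size, single positions, fragments in place of calls, scaling, test, replicate number as a block, library name prefix, the libraries in the fit and leaving out each library. The form of the main test was settled after window counts from limma voom, limma with a trend and a simpler quasi-likelihood fit had been seen, and it was kept as closest to the plan. On the simulated 4-fold changes limma voom recovered 112 of 200 windows with 7 false calls, a lower false share than the main test. The form of the main test, the main filter, limma voom, the 4-fold minimum, fragments, and the spanned share with its gap, scale, pseudocount and minimum mean of spanning fragments were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tabulation, permutation tests and plots.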

Results

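CpG methylation was profiled in leaves of 2 chickpea genotypes at the shoot apical meristem stage, to look for drought-responsive differences in a sensitive genotype (ICC283) and a tolerant one (ICC8261). Each of the 4 groups of genotype and water label had 3 libraries. The ICC283 WW libraries held 5687641, 4441062 and 3007851 methylated calls, and the ICC283 DS libraries 2738058, 3978858 and 4633870. The ICC8261 WW libraries held 4749296, 3922658 and 3141669, and the ICC8261 DS libraries 1781560, 3697233 and 1891970. Genotype and water are given below as the labels state them.

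The libraries separated by water label and not by genotype label. Across the 110038 tested windows, log2 CPM correlated at a mean r of 0.664 between libraries with the same genotype and water label. The mean was 0.663 between libraries that shared only the water label, and 0.453 between libraries that shared only the genotype label. The first principal component held 31.6% of the variance, with all 6 WW libraries between -0.44 and -0.39 and all 6 DS libraries between 0.29 and 0.57. These correlations are across windows, which are not independent replicates.

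**Figure D1:**
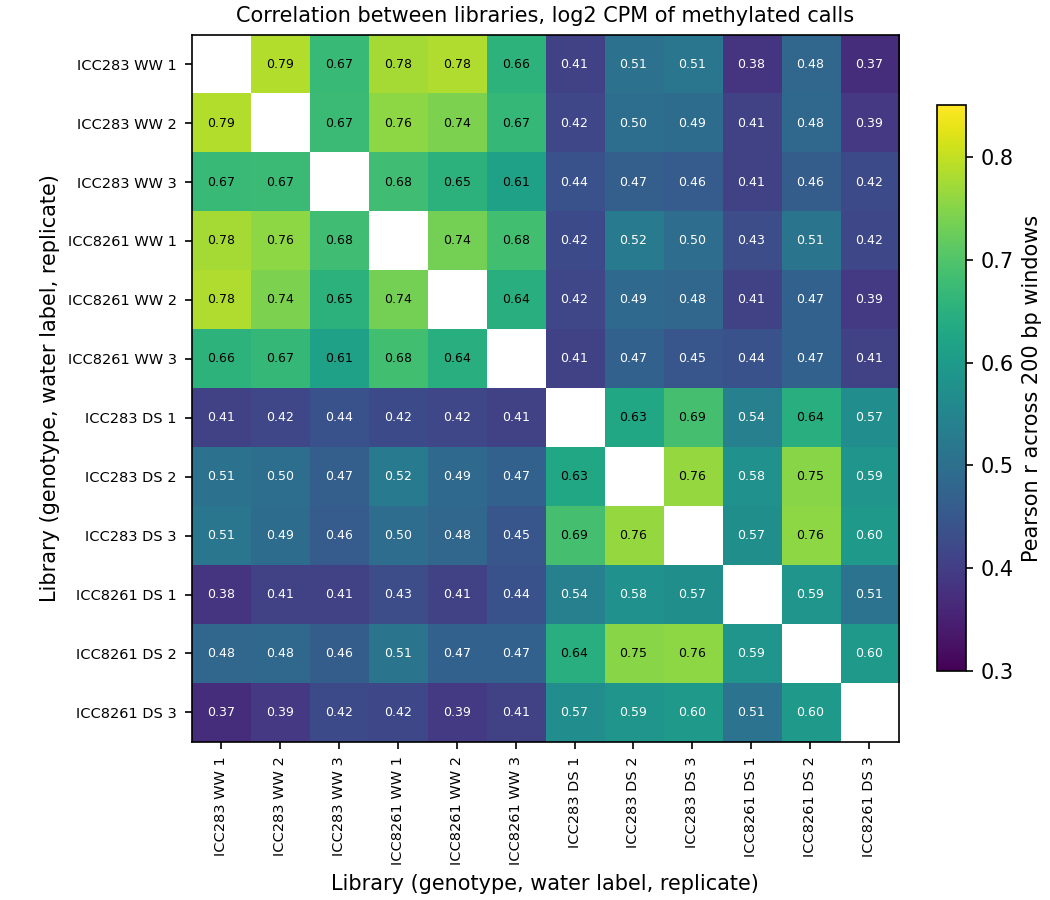
Pearson correlation of log2 CPM of methylated calls across 200 bp windows between each pair of the 12 libraries, ordered by water label; colour and number give r. Pairs with the same water label have r from 0.51 to 0.79 whatever their genotype label, and pairs with different water labels have r from 0.37 to 0.52.

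In ICC283, 1350 windows carried more methylated calls under drought and 2088 carried fewer, out of 110038 tested (quasi-likelihood test, Benjamini-Hochberg adjusted). The largest changes were between presence and absence. A window on Ca4, from 35310001 to 35310200, had no call in the 3 WW libraries and 53.2 CPM ± 5.46 (SD, n = 3) in the DS libraries, at least 174-fold higher, with an adjusted p of 8.8e-07 from the limma-moderated fit. Windows at 29453201 to 29453400 on Ca2, 29808401 to 29808600 on Ca3, 36377201 to 36377400 on Ca4 and 24152801 to 24153000 on Ca5 also had no call when well-watered. They reached 51.3 ± 8.71, 35.4 ± 6.63, 33.9 ± 4.16 and 33.6 ± 6.87 CPM under drought (SD, n = 3). Among windows with fewer calls, the one at 33305601 to 33305800 on Ca1 went from 45.2 ± 3.49 CPM to no call (SD, n = 3), at least 130-fold lower. The next were at 35844201 to 35844400 on Ca4, 39068801 to 39069000 on Ca1, 35208001 to 35208200 on Ca7 and 29143801 to 29144000 on Ca2. Their WW values were 40.6 ± 6.55, 39.6 ± 6.86, 38.8 ± 3.71 and 34.7 ± 3.91 CPM (SD, n = 3), and none had a call in the DS libraries. The DS group had no call in 716 of the 2088 lower windows, and the WW group had none in 315 of the 1350 higher ones. The p-values of such windows, here and in ICC8261, may be too small, since an empty group adds nothing to the residual spread. limma voom called 232 higher and 199 lower windows, and a minimum of 10 calls in every library left 52 higher and 26 lower, so that the excess of lower windows depends on the test and the filter. Without WW replicate 1, the only ICC283 library whose name starts with S1, 2895 windows passed.

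In ICC8261, 1184 windows carried more methylated calls under drought and 1939 carried fewer. The window at 29453201 to 29453400 on Ca2 had no WW call and 62.9 ± 21.6 CPM under drought (SD, n = 3), at least 173-fold higher, with an adjusted p of 4.2e-06 from the limma-moderated fit. The windows at 35310001 on Ca4, 36377201 on Ca4 and 29808401 on Ca3, named above, were again among the 5 with the largest rise, with 60.2 ± 18.7, 38.0 ± 15.9 and 38.2 ± 18.2 CPM (SD, n = 3). The fifth, at 41252401 to 41252600 on Ca1, reached 38.4 ± 6.25. The largest losses were again at 33305601 on Ca1, 35208001 on Ca7 and 35844201 on Ca4, which fell from 49.97 ± 2.51, 45.7 ± 3.83 and 45.1 ± 8.77 CPM to no call (SD, n = 3). They were followed by 39381401 to 39381600 on Ca1 and 44898601 to 44898800 on Ca4, with 39.7 ± 4.15 and 38.0 ± 2.70 when well-watered and no call under drought. limma voom called 102 windows, with 76 higher and 26 lower, and a minimum of 10 calls in every library left 39 higher and 13 lower. All ICC8261 WW libraries have names starting with S1 and all ICC8261 DS libraries names starting with S4. The name prefix and the water label therefore cannot be told apart within ICC8261 alone. ICC283 WW replicates 2 and 3, named S4, correlated at 0.614 to 0.757 with the ICC8261 WW libraries. With the ICC8261 DS libraries, also named S4, they correlated at 0.392 to 0.484, which argues against the prefix as the main divide between libraries. With the prefix as a covariate over all 12 libraries, 92 windows were higher and 1195 lower. The prefix effect then rests on ICC283 WW replicate 1 against replicates 2 and 3 alone. Where the WW libraries hold no call, it cannot be estimated, and the fit can give the rise in ICC8261 to the prefix. Such windows cannot pass, so the fall in higher windows is set by the design at least in part. Of the 1184 higher windows of the main test, however, 305 had no call in ICC8261 WW, and the lower windows fell as well, from 1939. The cause of the rest of the fall was not tested, and a dependence on the prefix stays open there.

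The drought comparisons of the 2 genotypes called overlapping sets of windows. They share no library as labelled, but 2 library names, up to their last number, occur in both ICC283 DS and ICC8261 DS. The libraries of these 2 pairs had different index sequences and 0 fragment names in common, so they are separate libraries; whether they come from separate plants is not known. Of the higher windows, 1002 were shared, against 14.5 for independent lists of that size. Of the lower windows, 1586 were shared against 36.8, and 2 windows were called in opposite directions. Both comparisons came from 1 fit, with 1 moderated variance per window and 1 filter. Some overlap may therefore arise without a shared change, and the numbers for independent lists may be too low. Called windows were gathered in parts of the genome. On Ca4, 7.30% of 13484 tested windows were called in at least 1 genotype, against 2.13% of 15955 on Ca5. In 1 Mb bins with at least 100 tested windows, the median share was 2.33%. It rose to 35.6% between 37000001 and 38000000 on Ca4, 37.6% in the next bin up to 39000000, 30.1% between 44000001 and 45000000 on Ca4 and 28.0% between 33000001 and 34000000 on Ca7. In 1000 shuffles of the calls over windows, no bin exceeded 12%. Across the 347 bins, the shares of the 2 genotypes correlated with Pearson's r of 0.987 and Spearman's rho of 0.872, over bins that are not independent replicates. At Ca4 37000001 to 39000000, higher windows prevailed, with 54 higher and 8 lower in the first of these bins in ICC283. At Ca7 33000001 to 34000000, lower windows prevailed, with 1 higher and 46 lower. Windows called in the same direction in both genotypes were joined when at most 1000 bp apart, so that a region can include windows that did not pass. The longest region lower in both genotypes covered 3600 bp on Ca7, from 35246401 to 35250000, with 8 called windows. The region with the most windows higher in both covered 2800 bp on Ca4, from 35654201 to 35657000, with 7.

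**Figure D2:**
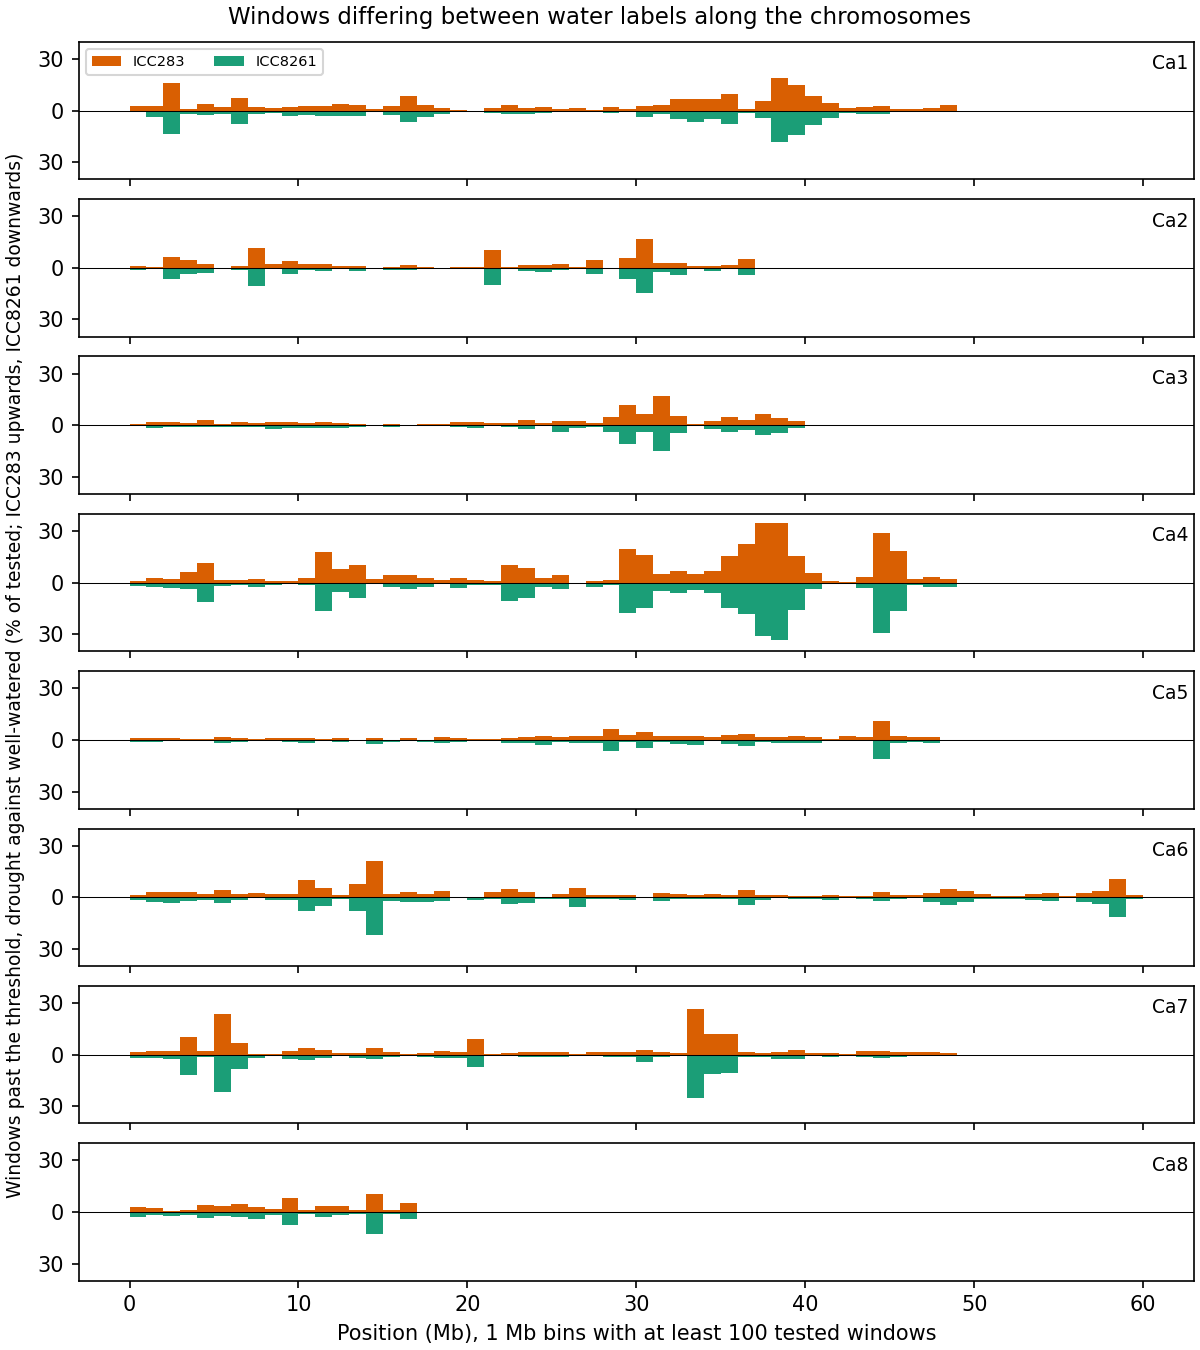
Share of tested 200 bp windows past the threshold for drought against well-watered in 1 Mb bins along Ca1 to Ca8, in percent, with ICC283 drawn upwards and ICC8261 downwards. Both genotypes have their highest bins between 37 and 39 Mb on Ca4, at 34.4% and 34.5% in ICC283 and at 31.1% and 33.5% in ICC8261.

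Between the genotypes, no window passed the threshold in well-watered plants (smallest adjusted p of 0.326), and 5400 of 110038 had an unadjusted p under 0.05, 4.91% of them. Under drought no window passed (smallest adjusted p of 0.073), with 6097 at an unadjusted p under 0.05. limma voom called 0 in both comparisons, and limma on log2 CPM with a trend called 0 and 26. The drought response differed between the genotypes in 0 windows (smallest adjusted p of 0.181, 4322 at an unadjusted p under 0.05), and in 0 by both limma fits. In data simulated for the genotype comparisons, 71.5% of 200 windows changed 4-fold were recovered when well-watered and 57.0% under drought, against 3.5% and 0.5% of 200 changed 2-fold, so that 2-fold differences would mostly be missed. The difference in drought response was not simulated.

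Single CpG positions gave the same division. With at least 3 calls in each library of one set and none in the other, 4766 positions had calls only in the 6 WW libraries. A further 1595 had calls only in the 6 DS libraries, while 0 divided the libraries by genotype label. The libraries with the fewest calls, ICC8261 DS replicates 1 and 3, make this minimum harder to reach on the DS side, so no excess is claimed. With at least 1 call, the numbers were 14337 and 6704 by water label. By genotype label, 271 had calls only in ICC283 and 7 only in ICC8261. Among 38963 positions spanned by at least 10 fragments in each group, 35 had a spanned methylated share of at least 80% in both WW groups and at most 20% in both DS groups. A further 18 had the opposite, and 0 followed the genotype labels. Position 31106273 on Ca1 had 100% of 18 and 22 spanning fragments methylated in ICC283 WW and ICC8261 WW, and 0% of 14 and 14 in the DS groups. Position 25875130 on Ca3 had 0% of 30 and 28 in the WW groups and 100% of 21 and 23 in the DS groups; these examples were chosen after their values were seen. By limma, 32 of 35795 positions had a higher spanned share under drought in ICC283 and 82 a lower one. In ICC8261, 28 were higher and 79 lower, and without DS replicate 2, the deepest of its group, 27 were higher and 331 lower. The arcsine scale, which does not rise with depth, gave 42 higher and 58 lower in ICC283 and 41 and 38 in ICC8261, so that no excess of lower positions is claimed. The genotypes shared 22 higher and 51 lower positions, against 0.025 and 0.181 for independent lists. These lists too came from 1 fit, so the numbers for independent lists may be too low. No position passed between genotypes under either water label, with 901 at an unadjusted p under 0.05 when well-watered and 3043 under drought. Under drought this hung on single libraries, with 23 positions without ICC8261 DS replicate 2 and 6 without ICC283 DS replicate 2. The arcsine scale called 43 and 17 positions.

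**Figure D3:**
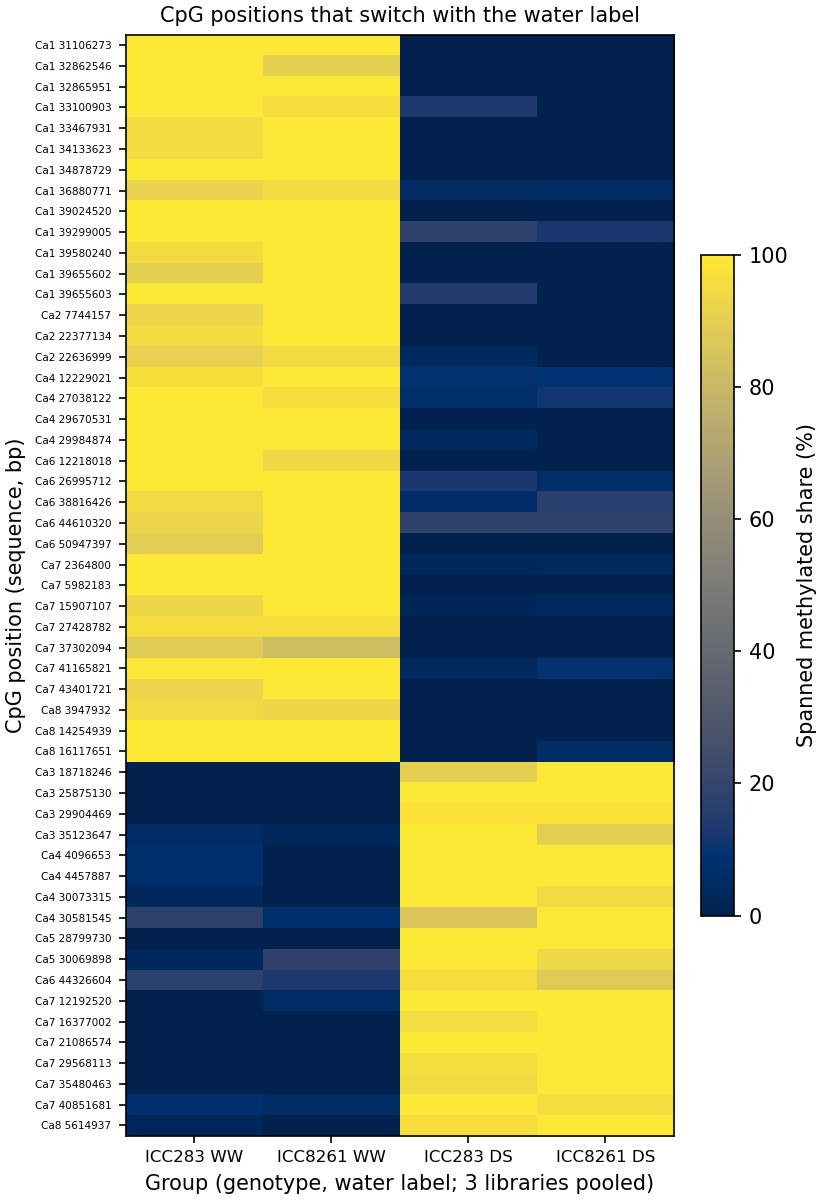
Spanned methylated share, in percent, of the 53 CpG positions that switch with the water label, with 3 libraries pooled per group. The upper 35 positions lie at 80% or more in both WW groups and at 20% or less in both DS groups, and the lower 18 show the reverse.

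The spanned methylated share over the genome was near its ceiling in every group, so that it says little about the level of methylation. It was 96.2% ± 0.152 in ICC283 WW, 96.2% ± 0.0242 in ICC283 DS, 96.0% ± 0.0454 in ICC8261 WW and 96.1% ± 0.223 in ICC8261 DS (SD, n = 3). Drought against well-watered gave exact permutation p-values of 0.7 in ICC283 and 0.6 in ICC8261, where 0.1 is the smallest possible. Over both genotypes, drought minus well-watered was 0.053 points, which did not pass (exact permutation p = 0.485), and 0.559 and 0.759 points over the positions with at least 10 and 20 spanning fragments in every library (exact permutation p = 0.01 and 0.015, not adjusted). ICC8261 minus ICC283 came to -0.154 percentage points, a difference that did not pass the test (exact permutation p = 0.08, adjusted 0.356). With every library thinned to 1770000 nuclear calls, 817932 ± 34312 distinct positions carried calls in ICC283 WW and 793479 ± 23146 in ICC283 DS (SD, n = 3, exact permutation p = 0.4). In ICC8261 the numbers were 804050 ± 30465 when well-watered and 755609 ± 16620 under drought (SD, n = 3, exact permutation p = 0.2). Over both genotypes the exact permutation p for drought was 0.055, adjusted 0.356, and that between genotypes was 0.125. For total methylated calls, drought against well-watered gave exact permutation p-values of 0.5 in ICC283 and 0.2 in ICC8261, where 0.1 is the smallest possible. Over both genotypes the exact permutation p was 0.115, adjusted 0.356, which did not pass.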

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

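Calls on the plastid sequence are part of the total methylated calls compared above, and no other comparison above uses them. They were present in every library, from 0.219% of all calls in ICC283 DS replicate 3 to 0.623% in ICC8261 DS replicate 1. The fewest plastid calls in a library were 6577, against a limit of 3 for a count of 0. The mean share was 0.297% ± 0.0176 in ICC283 WW, 0.252% ± 0.0369 in ICC283 DS, 0.462% ± 0.0237 in ICC8261 WW and 0.416% ± 0.182 in ICC8261 DS (SD, n = 3). ICC8261 lay 0.165 percentage points above ICC283, with an exact permutation p of 0.01 that came to 0.16 after adjustment; this test was chosen after seeing the data. No explanation was tested.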

How the results depend on the processing

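Of 370 alternative values, 317 kept their direction and their side of the threshold, or a count within 1.5 times. Part of these outcomes was fixed in advance. Within a genotype there are too few libraries for an exact permutation test to pass, so such values could change only in direction. A stricter minimum change cannot raise a count of 0 windows. The 317 therefore does not measure how robust the results are. The filter moved the drought counts most. It also moved the number of windows tested, which was 110038 in the main test. In ICC283 and ICC8261 the counts were 6666 and 5998 of 180233 with a mean of at least 5 calls, and 989 and 928 of 51535 with 20. With at least 10 calls in every library they were 78 and 52 of 34391 (52 and 39 of them higher), and with no filter 12344 and 8997 of 511306. Single CpG positions gave 117 and 102 of 25296 positions, and fragments in place of calls 663 and 701 of 48920 windows. Over the 110038 windows, limma voom gave 431 and 102, with 53.8% and 74.5% of them higher, where the main test had 39.3% and 37.9%. The prefix as covariate gave 1287 in ICC8261, where the design bars windows without WW calls from passing. In the main test, 305 of the 1184 higher windows had no call in ICC8261 WW. The causes of the rest of that fall and of the other changes were not tested. Between genotypes when well-watered, 1 window passed with a mean of 5 calls, 1 with 10 calls in every library and 4 with no filter. Under drought, 2 passed with no filter, 4 with only the 6 libraries compared and 26 by limma with a trend. For the difference in drought response, 1 passed with a mean of 5 calls and 2 with no filter.

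Leaving out single libraries gave 2856 to 3273 windows in ICC283, 2498 to 2929 in ICC8261, 0 to 1 between genotypes under drought and 0 to 1 for the difference in drought response. Positions by spanned share ranged from 74 to 358 in ICC8261 (358 without DS replicate 2), from 0 to 2 between genotypes when well-watered, from 0 to 23 under drought (23 without ICC8261 DS replicate 2) and from 0 to 2 for the difference in drought response. With a mean of 10 spanning fragments, 11 and 6 positions passed. The arcsine scale called 43, 17 and 38 positions in the last 3 comparisons. Other splits of the libraries of the same comparisons gave up to 45, 25 and 41 on that scale, so those counts are within its own errors.

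The ICC8261 minus ICC283 spanned share became 0.010 points over positions with 10 spanning fragments in every library and -0.153 with a gap of at most 30 bp (exact permutation p = 0.02), and ranged from -0.200 to -0.092 with single libraries left out, with exact permutation p of 0.035 without ICC283 WW replicate 2 and 0.01 without ICC8261 DS replicate 2. Over both genotypes, drought minus well-watered was 0.559 and 0.759 points over positions with 10 and 20 spanning fragments in every library (exact permutation p = 0.01 and 0.015), the first over 638 positions and the second over fewer. With single libraries left out, drought minus well-watered spanned from -0.055 to 0.097 points in ICC283 and from -0.00723 to 0.207 in ICC8261. Distinct positions spanned from -39257 to -5651 in ICC283 (-5651 without WW replicate 1) and from -45001 to -27046 over both genotypes, where 3 of 12 such settings took the exact permutation p from 0.055 to 0.02 or 0.03. Without single libraries, total calls spanned from -1280756 to 59139 in ICC283. The plastid share, drought minus well-watered, ranged from -0.149 to 0.023 points in ICC8261.

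The replicate block gave 3221 windows in ICC283 and 2980 in ICC8261 and changed no call of the other comparisons; same-numbered libraries correlated from -0.101 to 0.072 in their deviations, so the numbers do not pair them. Not run, for lack of unmethylated calls or of an annotation of this build, were percentage differences per window, ratios and logistic models per window, and every gene, promoter and gene list alternative; a second count package was not run because the unit does not allow it.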

Other observations

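For the first pattern, the tests of coverage, partner strand and library prefix were set out before their results were seen, and the partner test was limited to the spanned positions after; the coverage test among spanned positions, the bounds of 20% and 50% for partners, the first tried after the second, the splits of the libraries, the partner test of the second pattern and the test of exchanged labels were chosen after. In the 10 splits of the 6 libraries of a comparison, which are too few for a share under 0.05, the labelled split gave 3438 windows in ICC283 and the highest other 0, and in ICC8261 3123 and 3; as many windows came from 1 split in each. Between genotypes the labelled splits gave 0 windows, with highest others of 2 when well-watered and 3 under drought, and the difference in drought response gave 0, with a highest other of 25. A count of 0 is reached by every split, here 10 of 10 and 20 of 20, so that these splits test nothing. Positions by spanned share were 32 higher and 82 lower in ICC283 and 28 higher and 79 lower in ICC8261, against 0 in every other split of either genotype. The arcsine scale called 17 to 39 in the other ICC283 splits and 11 to 27 in the other ICC8261 splits, against 100 and 79 in the labelled ones. On the log2 scale there were 0 between genotypes against at most 4 when well-watered. Under drought another split gave 127; it sets the 3 libraries with the fewest calls against the 3 with the most, where the log2 ratio moves with depth, and the arcsine scale gave 19 there, within the 10 to 25 of all 10 splits. For the difference in drought response the highest other was 1.

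A first pattern is the 6361 CpG positions with calls in all libraries of one water label and in none of the other. Of all 462 splits of the 12 libraries into 6 and 6, 1, the labelled one, gave as many, and the highest other gave 6. This argues against chance as the source of the division. The library name prefix parted 6 positions, far fewer than the water labels, which argues against that batch. At least 10 fragments of the libraries without calls spanned 0.69% of the 5940 positions with a strand. The bound set for that share was out of reach, since the libraries with calls spanned only 15.9%, and it decides nothing. Of the 944 positions spanned there, the libraries without calls spanned 4.03%. Among positions called in every library, the DS libraries spanned 98.9% of those spanned in WW libraries. Those positions were chosen for their calls, which fixes a high value in advance, so the comparison decides nothing. A gap in coverage may account for nearly all of the 944, and the loss of every methylated fragment at a site would look the same in lists of methylated calls. Of 18 partner cytosines read in the libraries without calls, 38.9% had a share of at least 10% (95% binomial confidence interval 17.3% to 64.3%), where the positions themselves had no call. This is consistent with a sequence difference and argues against a loss copied to both strands as the cause of all of them. Of the 18, 13 had at most 20%. The 5 others, 4 of them with at least 50%, argue against such a loss at their positions. It stays open at the other 36 of the 41 spanned positions.

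A second pattern is the 53 positions read in all 4 groups that switch with the water label. At the library level, 22 of 18436 positions did so, and 1 of 462 splits gave as many, with 0 in the highest other. This argues against chance as the source of the division at those 22. The 53 pooled positions were not tested over splits. The cytosine of the other strand had a share of at least 10% at 40% of 20 positions that could be read, with a median of 8.33%. Since a switched position itself counts as lost up to 20%, that bound shows no kept partner and decides nothing for this pattern. By the limit of 20%, 15 of the 20 partners were lost as well. At the other 5 the partner had at least 50%, which a drought response copied to both strands forbids at those 5; it stays open at the other 48. A base change in 1 cytosine of the CpG stays open as well. It could lie in the position itself at the 28 that had no call in the low groups. At the other 25 some calls remained, which a change of the partner would leave and a change of the position itself would not. These calls could be few. At 30073315 on Ca4 and 5614937 on Ca8, they were 3.70% of 27 and 2.86% of 35 spanning fragments in ICC283 WW, and 0% in ICC8261 WW. So few calls decide little against a change of the position. The partners there were 89.3% and 100% methylated, which a change of the partner forbids. Of the 20, 7 had been read for the first pattern, so the 2 tests are not independent; of the 13 others, 6 had at least 10%. Exchanged labels of genotype and water are a candidate explanation, because 2 accessions should differ in sequence and 0 positions read in all 4 groups switched with the genotype labels. The plastid share does not settle this. It followed the genotype labels more closely than the water labels. By genotype label it differed by 0.165 points (exact permutation p = 0.01, adjusted 0.16), and by 0.113 to 0.199 points with single libraries left out. By water label it differed by -0.0456 points (exact permutation p = 0.41, adjusted 0.596). The largest such difference with a library left out was -0.0973 points, without ICC8261 DS replicate 1 (exact permutation p = 0.01, not adjusted). However, ICC8261 DS replicate 2, at 0.278%, lay within the ICC283 libraries. Another candidate explanation is that the plants behind the WW and DS labels came from different seed. The calls cannot tell these explanations apart, and no library was moved to another group.

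If the labels stand, a drought response on top of a sequence difference is untested, since both would coincide with the water labels. If the labels were exchanged, the genotype comparisons above would be the drought comparisons, and these called 0 windows and 0 positions, with 2-fold changes mostly missed in simulated data.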
